A study of Haloferax volcanii DS2 with 8 samples.

How the data were processed

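The study comprised 8 libraries of 6 groups, mapped to groups by their titles, all ribosome profiles except 1 library of total RNA treated with the nuclease. Cultures were grown at a single temperature, harvested by centrifugation or direct freezing, lysed with anisomycin in the buffer, digested with micrococcal nuclease and run on sucrose gradients, per the labels' protocols. The protocols name the strain H98 and the sample characteristics name DS2. Reads were handled with Trim Galore and Bowtie 0.12.7, per the submitters' processing notes, which give no roles or settings. 4 of the groups had 1 library and the other 2 had 2 libraries.

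The authors deposited 1 annotation for the whole series, and its values are coordinates, the 1-based start and end of each feature in nt, with no normalization and no value per library. Per the file headers, it was written by the NCBI annotation writer for the genome build ASM2568v1. Per the file's source column, 84 coding records came from RefSeq under older locus tags, 2875 from protein homology and 9 from GeneMarkS+, and 32 intergenic RNAs came from StringTie. How the additions were chosen is not given in the sources used here. The column of starts and the column of ends were read, and 0 columns of per-sample values were left out. As there were no library values, the comparisons between groups were not made.

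The file gave no transcript starts apart from coding starts, and no genome sequence was used here. The planned results on leaderless share, leader length, Shine-Dalgarno matches, start codons, promoter AT content, folding energy and serine codons were therefore not made, and the neighbourhood was compared between gene lists in place of leader classes.

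Coding records were joined to genes by identical start, end and strand, which matched all 2968. Joining by parent ID would mix genes, because 83 gene IDs and 83 coding IDs were used more than once and 80 parents had more than 1 coding record. Records under pseudogenes were left out, which left 2912 coding genes, all with lengths that are multiples of 3. Genes without the RefSeq style of locus tag, which follow after the others in the file, were taken as added. The reference was the RefSeq gene table of the same assembly, with 3019 genes on the chromosome. It gives no strand, so the file's strand was used. Genes were matched by locus tag (2779) or, where the tag was not in the table, by the coordinate of the stop codon with a length difference of whole codons (70); 63 coding genes were not compared. A reference gene counted as found only in the reference when it shared no tag or stop codon with the file and under 50% of it was covered by the file's genes. Symbols were taken from this table, which gave one to 388 of the coding genes.

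Genes were ordered by their midpoints on the circular chromosome. A gene was close behind its upstream neighbour when both lay on the same strand and fewer than 50 nt separated them, overlaps included. Gene lists were patterns on the product text, 20 in all, fixed before the data were examined, and 19 had members. Shares carry exact Clopper-Pearson 95% intervals. Lists were compared with all other coding genes by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the lists, with a threshold of 0.05. Because genes of a cluster are not independent, for close neighbours the list was also rotated through every position of the gene order, which gives a smallest p of 0.000343. For overlaps of 4 nt the rotation ran along the order of close genes. The tests of starts by gene list were not repeated by rotation. Overlaps of 4 nt were compared between lists with at least 10 close members. Median lengths were compared by a two-sided permutation test with 100000 resamples. Not in the plan were the tests of added genes, of overlaps and of starts upstream against downstream. The tests of starts and of close neighbours by gene list were not planned either.

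Alternatives fixed beforehand were matching by stop codon only for the number of differing starts, and limits of 20 and 100 nt for the share of genes with a close neighbour. Added after the data were seen were the use of these 2 choices for the gene lists and for the share of starts upstream, matching by locus tag only, leaving out hypothetical proteins, leaving out added genes or overlapping added genes, the rotation, lists without members that a pattern took by mistake, and the cobalamin list without these and without transporters. The genes named were the 10 with the largest start shift and known genes fixed in advance, of which the reference gave symbols for 14 of 35, as 15 records. The part of that rule based on leaders had no values. In its place, chosen after the file was seen, stand the first 2 members of each list along the chromosome with and without a close neighbour, from which examples were taken. Other genes are said in the text to have been chosen after their values were seen, and runs of genes are the 4 longest and others chosen after their contents were seen.

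The steps were tested on simulated data. With 5 lists raised to 60% against 25% in 2912 genes, 99.4% of planted lists were recovered over 100 simulations, and 2% of simulations without planted lists called any list. Each simulated gene was drawn independently, so these rates do not cover the clustering of close genes in the file. For the start comparison, 200 planted shifts in 2779 genes matched by locus tag were all returned with their size. The reference copy was made from the file's own coordinates, so this checks only the arithmetic and the sign of a shift. Matching by stop codon was not tested in this way. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.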

Results

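Ribosome profiling, which sequences the mRNA fragments that ribosomes protect from nuclease, was carried out in the halophilic archaeon Haloferax volcanii. The 8 libraries fell into 6 groups. Cells were harvested by centrifugation (2 libraries) or by freezing the culture directly in liquid nitrogen without a drug (2 libraries). A single library each came from frozen cultures treated with anisomycin at 100 µg/mL, with homoharringtonine at 1 mg/mL and with serine hydroxamate at 20 mM, and 1 library came from total RNA cut with micrococcal nuclease. Anisomycin blocks peptide bond formation, homoharringtonine is used to hold ribosomes at the start of translation and serine hydroxamate inhibits the charging of tRNA-Ser. The deposited file was a single annotation for the whole series, of the main chromosome apart from 12 intergenic RNAs on other replicons, with no value for any library, so no level, pause or difference between these groups was analysed here, and the depth of the libraries is unknown. The units counted below are genes of this annotation, and intervals cover counting error only.

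The annotation described 3028 gene and pseudogene records on a chromosome of 2847757 bp, of which 2912 were intact coding genes, 1416 on the plus strand and 1496 on the minus strand. Products called hypothetical or of unknown function made up 1021 coding genes (35.1%). The stable RNA genes comprised 52 tRNA genes covering all 20 amino acids, 6 rRNA genes in a pair of operons, the RNA of the signal recognition particle and the RNA of RNase P. The 4 tRNA-Ser genes, whose product serine hydroxamate keeps uncharged, lay at 408343 to 408423 and 2620287 to 2620371 on the minus strand and at 575668 to 575752 and 2626534 to 2626617 on the plus strand. serS (HVO_RS13905), which encodes the enzyme that charges them, lay at 1770475 to 1771857 on the plus strand. The longest tRNA genes, chosen after their lengths were seen, were tRNA-Trp (177 nt), tRNA-Met (149 nt) and tRNA-Gln (103 nt), against a median of 74 nt over all tRNA genes.

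The file listed 2828 coding genes under RefSeq locus tags and a further 84 under older ones, which followed after the others together with tRNA-Trp at 1165741 to 1165917 and are called added here. The question was what kind of genes they were. The added coding genes were short. Their median coding length was 159 nt (quartiles 138 and 177 nt), against 741 nt (441 and 1122 nt) for the others, a difference of -582 nt (permutation test, p = 1e-05, the smallest that 100000 resamples can give). Of the 84, 71 (84.5%, 95% exact binomial interval 75.0 to 91.5%) were 210 nt or shorter, against 108 of the others (3.82%, 3.14 to 4.59%; Fisher's exact test, p = 8.35e-79). Hypothetical proteins made up 75 of the 84 (89.3%) and 946 of the others (33.5%; Fisher's exact test, p = 1.19e-25).

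Among the 9 added genes with a described product, 5 encoded zinc finger proteins, a fold in which cysteine or histidine residues hold a zinc ion. These genes were named after their values were seen. HVO_0197A (178195 to 178344), HVO_1848A (1708467 to 1708622), HVO_2805A (2636917 to 2637075) and HVO_2901 (2738566 to 2738730) were described as small CPxCG-related zinc finger proteins, with 49, 51, 52 and 54 codons before the stop. HVO_1326 (1206493 to 1206627) was described as a putative C2H2 zinc finger protein of 44 codons. In the RefSeq table of the same assembly, all 5 were present with the same start and stop. Over all added genes, 57 of 84 (67.9%, 56.8 to 77.6%) shared their stop codon with a protein-coding gene of that table, 49 of them with the same start, and 27 had no such partner.

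Most added genes stood alone: 64 overlapped no other gene, 15 overlapped a gene on the same strand and 5 overlapped one on the opposite strand only. HVO_2286 (2150003 to 2151682, minus strand) was the long form of a gene whose short form, HVO_RS15700 (2150003 to 2150245), was also kept, the 1 stop codon that belonged to a pair of coding records. HVO_0410 overlapped HVO_RS06675 on the opposite strand by 387 nt, and HVO_1794 lay within HVO_RS20180 on the same strand over 408 nt. A close upstream neighbour, defined further down, was found for 13 added genes (15.5%) and for 709 others (25.1%), a difference that did not pass the threshold (Fisher's exact test, p = 0.0535).

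The coding starts of the file were then compared with the RefSeq table, since the study asked about other sites of translation initiation. Hypothetical proteins were the 1 list that passed the threshold: 65 of 974 (6.67%, 5.19 to 8.43%) had another start, against 52 of 1875 other genes (2.77%; Fisher's exact test, p = 1.99e-06, adjusted p = 3.78e-05 over 19 lists). This test treats genes as independent and was not repeated by rotation, although start differences were crowded in a region described further down. No ribosomal protein (0 of 58, up to 6.16%), respiratory chain gene (0 of 47, up to 7.55%), replication and repair gene (0 of 46, up to 7.71%) or aminoacyl-tRNA synthetase (0 of 18, up to 18.5%) differed, and none of these lists passed the threshold against the other genes. Sensor kinases differed in 4 of 31 genes (12.9%), which did not pass after adjustment (exact p = 0.0361, adjusted p = 0.343). All 15 records of the known genes fixed beforehand that the table names had the same start in both. Among them were csg (the S-layer glycoprotein), cetZ2 (a tubulin-like protein of cell shape), gyrA, gyrB, psmA, psmB, radA, secY, lonB and sod. The table gave symbols for 14 of the 35 fixed genes, so the result does not cover the others. Genes without a symbol, chosen after their values were seen, did differ. HVO_RS14370, described as cell division protein FtsZ, had a shift of -21 nt (downstream in the file). HVO_RS15305, described like cetZ2 as a cell division protein, had a shift of -12 nt. The product text does not show whether they are among the fixed genes.

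Over all genes, 117 of 2849 compared (4.11%, 3.41 to 4.90%) had a different start. Among those matched by locus tag, 103 differed, all by whole codons, and none had a different stop; for the others, matched by stop codon, the matching itself sets both. The file's start lay upstream in 46 genes (39.3%, 30.4 to 48.8%), by a median of 28.5 nt, and downstream in 71, by a median of 42 nt (exact binomial test against equal shares, p = 0.0261). This test was not planned and treats genes as independent. Start differences were, however, crowded in a region described further down, where most of them lay downstream. Without the hypothetical proteins the shares were equal (50.0%, exact p = 1), an alternative chosen after seeing the data. The shift was 30 nt or less in 53 genes and over 100 nt in 26. It is not known which of these starts the authors set and which differ between versions of the RefSeq annotation.

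Among the 10 largest shifts, the short record HVO_RS15700 began 1437 nt downstream of the reference gene, whose start was that of HVO_2286. HVO_RS15710 (2154109 to 2155278), HVO_2332 (2197892 to 2198029), HVO_RS14885 (1983562 to 1984137), HVO_RS13005 (1596084 to 1596653) and HVO_0527 (459341 to 459817), all hypothetical proteins, were shorter in the file by 558, 375, 258, 216 and 210 nt. The ATP-binding protein HVO_RS15715 (2155631 to 2157352) was shorter by 276 nt. The sensor histidine kinase HVO_RS18410 (2671351 to 2672361) was longer in the file by 354 nt, and the hypothetical proteins HVO_RS20230 (1899299 to 1901059) and HVO_RS11045 (1201909 to 1202355) were longer by 324 and 195 nt. A further 13 coding genes of the file were pseudogenes in the reference, among them HVO_RS07930 (a sulfite oxidase) and HVO_RS12920 (an MFS transporter), named after their values were seen.

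**Figure D1:**
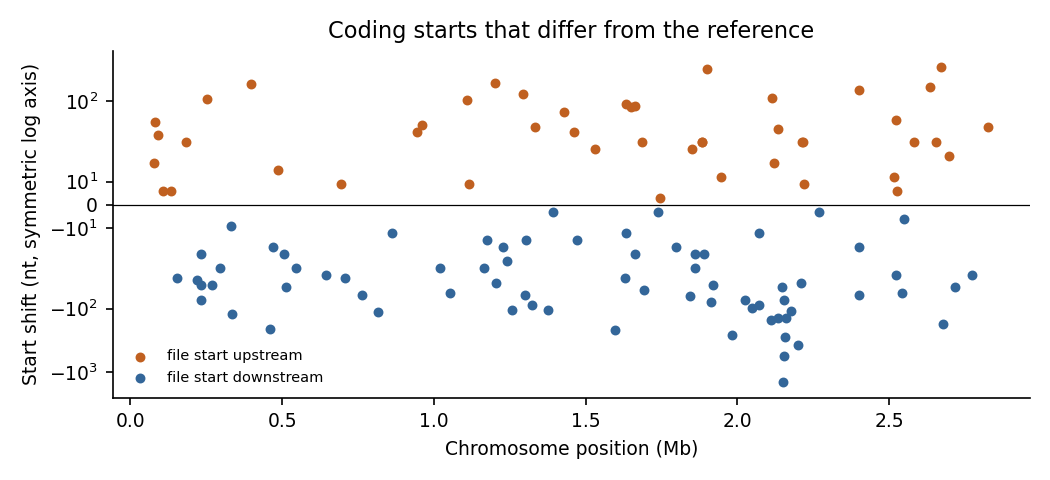
Each point is a gene whose coding start differed from the reference, at its position on the chromosome (Mb, x axis) with the shift in nt (y axis, symmetric log scale). Positive values are the 46 genes whose start lay upstream in the file and negative values the 71 whose start lay downstream.

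Of the 117 genes, 69 followed a gene on the same strand in the file, so that the choice of start sets the distance to it. Both starts were measured to this neighbour in the file, and genes found only in the reference were not considered as neighbours. With the file's starts 11 of the 69 were less than 50 nt from the file's neighbour, and with the reference's starts 19 were. Both counts include the short record HVO_RS15700, whose neighbour was HVO_2286, the long record of the same gene. A start that overlaps a true neighbour is thus not what put it there. By the same measure, a start that overlaps the neighbour's stop by 4 or 1 nt occurred in 2 of the 69 with the file's starts and in 6 with the reference's. It was gained in 5 genes and lost in 1, which did not pass an exact two-sided test of gains against losses (p = 0.219). CheF (HVO_RS10560), a chemotaxis protein that ends a cluster of flagellar genes and was named after its values were seen, overlapped its neighbour by 4 nt in the file and lay 101 nt away in the reference.

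The spacing of genes on a strand was compared between gene lists fixed before the data were examined. Ribosomal protein genes often sat close behind another gene: 40 of 58 (69.0%, 55.5 to 80.5%) had a same-strand upstream neighbour less than 50 nt away, against 23.9% of the other coding genes (adjusted p = 9.56e-12, Fisher's exact test). ABC transporters, which import or export solutes with ATP, had 68 of 120 (56.7%, 47.3 to 65.7%; adjusted p = 5.08e-13, Fisher's exact test). RNA polymerase and general transcription factor genes had 14 of 22 (63.6%, 40.7 to 82.8%; exact test, adjusted p = 0.000777). Transcription regulators, with 10 of 90 (11.1%, 5.46 to 19.5%; exact test, adjusted p = 0.00657), and transposases and integrases, with 3 of 39 (7.69%, 1.62 to 20.9%; adjusted p = 0.0322), lay close behind a neighbour less often than other genes. Fisher's exact test treats the genes of a cluster as independent, so its p-values overstate the evidence. All 8 lists past the threshold in that test kept it when the lists were rotated along the gene order, which respects the clustering of genes. By rotation the adjusted p was 0.0087 for ribosomal proteins, 0.00652 for ABC transporters and 0.0087 for RNA polymerase. It was 0.0147 for transcription regulators and 0.0424 for transposases and integrases.

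The remaining lists above the other genes were the respiratory chain and ATP synthase (22 of 47, 46.8%; adjusted p = 0.00462), archaella, pili and chemotaxis (20 of 44, 45.5%; adjusted p = 0.00793) and cobalamin biosynthesis (7 of 10, 34.8 to 93.3%; exact adjusted p = 0.0089). In the same order, the adjusted p by rotation was 0.0183, 0.0252 and 0.0252. Patterns also took members that do not belong to their lists, such as the electron transfer flavoprotein HVO_RS06170 in the archaella list, the magnesium and cobalt transporter corA in the cobalamin list and 3 excinuclease subunits of DNA repair in the ABC transporter list. The archaella call held without 12 such members, 4 of them close (exact test, adjusted p = 0.00797). The 2 taken by mistake in the cobalamin list and the 3 excinuclease subunits were not close, so leaving them out could not weaken those calls. Without its transporters as well, the cobalamin list had 4 enzymes, all close and in 1 run (exact test, adjusted p = 0.0102; by rotation, adjusted p = 0.0489). With a limit of 100 nt in place of 50 nt the calls for RNA polymerase, archaella and cobalamin ended (exact tests, adjusted p = 0.0811, 0.105 and 0.112), and with 20 nt the call for transposases ended (exact test, adjusted p = 0.127). The other 11 lists did not pass the threshold, among them translation factors (3 of 14), aminoacyl-tRNA synthetases (4 of 18), proteasome and chaperones (4 of 21), central carbon metabolism (11 of 45) and amino acid biosynthesis (20 of 60), and the CRISPR-Cas list had 0 members on the chromosome.

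**Figure D2:**
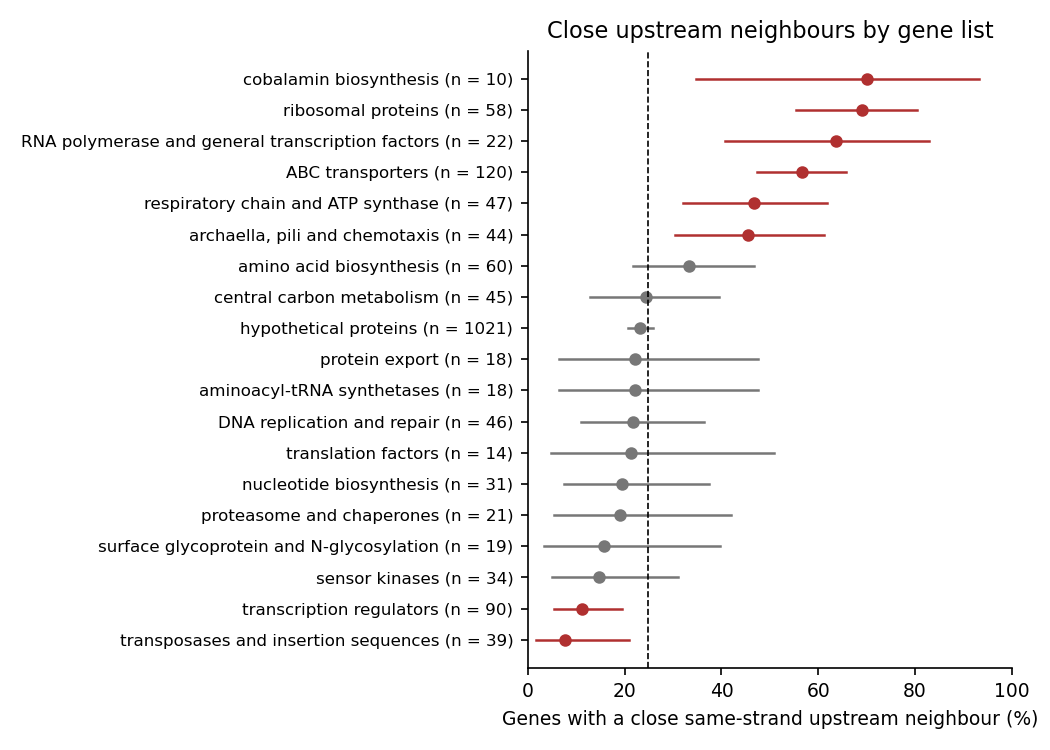
Share of genes with a same-strand upstream neighbour less than 50 nt away (%, x axis) for 19 gene lists (y axis), with 95% exact binomial intervals as lines. The dashed line is the share over all coding genes (24.8%), and red marks the 8 lists past the threshold in Fisher's exact test.

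The genes behind these shares formed runs. The longest, of 25 genes on the minus strand from 2406014 to 2420295, began at its 5′ end with a hypothetical protein and the ribosomal proteins L3 and L4 and ended with secY, the channel subunit of protein export, and 22 of its genes encoded ribosomal proteins. A run of 11 on the plus strand from 1633761 to 1642469 held an ArsR family regulator, 3 ABC transporter subunits and a leucyl aminopeptidase. Of the 2 runs of 8, that from 2140967 to 2148052 held 6 hypothetical proteins and that from 2614266 to 2617916 held 4 ribosomal proteins and RNA polymerase subunits. Some shorter runs were chosen after their contents were seen. A run of 7 from 137039 to 142417 held urease subunits and accessory proteins. A run of 7 from 1102755 to 1110353 held flagellar proteins and CheF, and a run of 6 from 281153 to 286554 subunits of the ATP synthase. Another run of 7, from 519896 to 525578, held a HAD family hydrolase followed by enzymes of cobalamin synthesis. The gene for RNA polymerase subunit B'' (HVO_RS06375) overlapped that for subunit H by 4 nt, rpoB began 1 nt after it, and gyrA began 1 nt after gyrB. In all, 1197 genes lay in 452 runs of 2 or more, 32 of which held 5 or more, and 1831 genes stood alone.

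By the same measure, single genes of several systems stood apart from their neighbours. csg followed its same-strand neighbour at 450 nt, radA at 258 nt, a thermosome subunit gene (HVO_RS05345, thsA) at 252 nt, serS at 177 nt and psmB at 148 nt, where the neighbour was the added gene HVO_1561. psmA, an alpha subunit of the proteasome, lay 6 nt behind its neighbour, and the other alpha subunit gene, HVO_RS18840, named after its values were seen, lay 159 nt behind its own. Of the first list members along the chromosome, the ribosomal proteins L31e (HVO_RS05255) and S7 (HVO_RS06410) followed at 3 and 2 nt, and L39e (HVO_RS05250) at 150 nt. glyS overlapped its neighbour by 8 nt and lysS followed at 1 nt. The integrase xerA followed at 1 nt and the integrase HVO_RS05955 at 456 nt.

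Over the chromosome, 722 coding genes (24.8%, 23.2 to 26.4%) had a close upstream neighbour, 1812 (62.2%) had an upstream neighbour on the same strand at any distance, and 370 overlapped it. An overlap of 4 nt, in which the start and stop codons share bases, was the most frequent, with 231 genes (62.4% of overlaps, 57.3 to 67.4%), followed by 1 nt with 67 and 8 nt with 34. Among close genes, 4-nt overlaps were more frequent in ABC transporters (34 of 68, 50.0%, against 30.1% of the others; adjusted p = 0.0128 over 10 lists) and in amino acid biosynthesis (13 of 20, 65.0%, against 31.1%; adjusted p = 0.0128), both by Fisher's exact test. Ribosomal proteins had 12 of 40 (30.0%), which did not pass (exact test, adjusted p = 1).

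**Figure D3:**
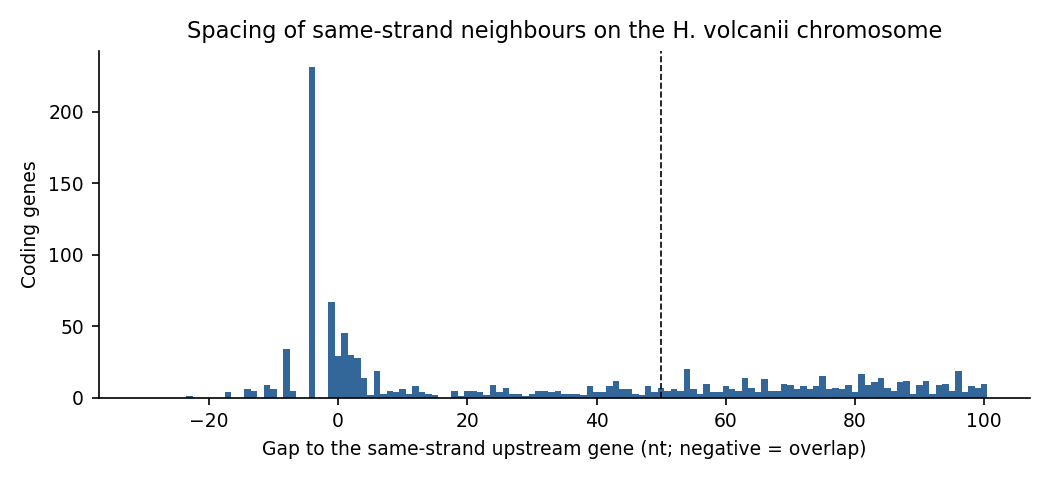
Number of coding genes (y axis) by the gap to the upstream gene on the same strand (nt, x axis, negative for overlaps, shown from -30 to 100), with the 50-nt limit dashed. The highest bar is the overlap of 4 nt with 231 genes.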

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

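No paired analysis was possible because the file holds no value per library. Settings fixed beforehand that need transcript starts or a genome sequence were not run: other limits for a leaderless start, leader length limits, Shine-Dalgarno, promoter, folding and serine codon settings, and the choice of genes for the leader classes. Fixed before were matching by stop codon for the number of differing starts and limits of 20 and 100 nt for the share of genes with a close neighbour; their use for gene lists and the share of starts upstream, and all other alternatives, were chosen after seeing the data. The number of differing starts was 117 by stop codon and 103 by locus tag. Without hypothetical proteins it was 52, as fewer genes were compared and these differed less often (2.77%), and the share of starts upstream in the file moved to 50% (exact p = 1). The share of genes with a close neighbour was 20% with a limit of 20 nt and 38.7% with 100 nt, as a wider limit takes more genes. With 100 nt, 5 lists passed the threshold in place of 8, and the adjusted p of the exact test was 0.0811 for RNA polymerase, 0.105 for archaella and 0.112 for cobalamin biosynthesis; with 20 nt it was 0.127 for transposases, and hypothetical proteins passed below the other genes (adjusted p = 0.0409). The cause of these changes was not tested. The shorter length of added genes held among hypothetical proteins alone (-288 nt) and without overlapping genes (-591 nt). The 4-nt overlap calls held without added genes and under rotation. No call changed direction. Depth limits nothing here that can be measured, since no counts were used.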

Other observations

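Of the tests in this part, the one over genes matched by locus tag was set after its count had been seen; for the others the pattern had been seen and the test's result had not, except that the limit on covered reference genes was set after a first run of the overlap test. The file lists 32 intergenic RNAs with StringTie as their source, 20 on the chromosome and 12 on other replicons, 76 to 1253 nt long with a median of 214 nt. The chromosomal s194, IG1.7 and Hts4 lack the STRG form of name, and whether StringTie assembled them is not known here. On the chromosome, STRG.2702 (988706 to 989251, plus strand) was the 1 RNA that overlapped a gene of the file, by 278 nt of HVO_RS09905 on the opposite strand. STRG.1903 (311962 to 312092, minus strand) began 2 nt from the start of the gene for RNA polymerase subunit H, HVO_RS06370, and ran away from it on the opposite strand. STRG.3072 (1299138 to 1299290, plus strand) began at the same base as HVO_RS20940, a protein-coding gene of 171 nt found only in the reference, whose strand the table does not give. These RNAs were named after their values were seen.

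The reference holds 41 genes on the chromosome with no counterpart in the file, 36 of them protein-coding, with a median length of 171 nt over all 41. Of the 19 chromosomal RNAs that lie wholly between the file's genes, 4 overlapped such a gene: STRG.3072, STRG.4070 and the neighbouring STRG.4082-2 and STRG.4082-3. The last 2 overlapped the same gene, HVO_RS20630, by 15 and 233 nt. STRG.4070, on the minus strand, overlapped HVO_RS20620, whose strand the reference does not give. By 443 nt it also overlapped the reference form of HVO_RS15710, which the file holds in a shorter form. HVO_RS15710 lies on the plus strand, so STRG.4070 runs opposite to it. Overlaps with genes found only in the reference were counted without regard to strand. A hypothesis was that these 4 RNAs mark small coding genes that the file lacks. Random placement between the file's genes gave a mean of 2.62 overlapping RNAs and reached 4 with a permutation p = 0.26. Placement of each RNA within its own gap gave a mean of 4.3 and a permutation p = 0.797, but it cannot decide the question. STRG.3072, for example, is 153 nt long and its gap leaves only 110 nt outside HVO_RS20940, so every placement there overlaps that gene. By placement between the file's genes, chance may account for the number of overlaps, and no biological explanation was tested.

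Start differences were crowded in a run of 50 compared genes from 2102738 to 2160219, where 11 genes differed, among them HVO_RS15710, HVO_RS15715 and HVO_RS15725, and 33 of the 50 were hypothetical proteins. Chance crowding does not account for it: shuffles over all compared genes had a median largest count of 7 and reached 11 with a permutation p = 0.0015. Nor, over all compared genes, does the excess of hypothetical proteins alone, since shuffles within hypothetical and other genes gave a permutation p = 0.0018. Among the 2779 genes matched by locus tag, which leaves out double records, the highest count in a run of 50 was 9 (permutation p = 0.024). These last shuffles did not keep hypothetical and other genes apart. Whether hypothetical proteins and double records together account for the crowding was therefore not tested. Revision of the reference in this region and an origin of the region outside the genome remain possible explanations that were not tested.

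In 2 of the 17 gaps with intergenic RNAs, the gap lay beside 1 of the 6 genes for the replication initiator Cdc6: STRG.4909 near HVO_RS04710, and the 3 RNAs of STRG.4082 beside HVO_RS20270. Random placement put RNAs into a mean of 1.48 such gaps and reached 2 with a permutation p = 0.456, so the hypothesis that these RNAs favour replication origins may be no more than chance.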
